A study of Homo sapiens with 417 samples.

How the data were processed

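Tissue sections of high-grade serous ovarian carcinoma, fixed in formalin and embedded in paraffin, were profiled with the GeoMx Digital Spatial Profiler and its human Whole Transcriptome Atlas. In this assay, probes with a photocleavable tag hybridise to RNA on the section, light releases the tags from a chosen region, and the released tags are sequenced. The sections were stained for CD20 (a B cell protein), CD45 (a protein of all leukocytes) and PanCK (epithelial cytokeratins), and the authors divided each region into segments by those stains. The labels name the segments CD20, Immune, Stroma, Tumor, Full ROI and Other. In total 417 segments from 20 specimens were analysed: 19 specimens from omentum, ovary and fallopian tube, and 1 from a non-malignant lymph node.

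The authors made probe counts with the DRAGEN GeoMx pipeline, version 3.8.4-96, on GRCh38.p13, and then ran segment and probe quality control and a normalisation to the third quartile in the GeoMx analysis suite, version 3.1.0.194. The deposited matrix holds a normalised signal: deduplicated counts multiplied by 1 factor per segment that brings the third quartile to a common value. Divided by the deposited factor, which is a ratio, 100% of the values of gene targets were whole numbers at a tolerance of 1e-06, and the lowest was 1. The third quartile of the signal had a median of 14.2 over segments and differed from that common value by over 0.001 in 4 segments. The deposited segment table also gives counts of raw and deduplicated reads, counts of nuclei, and the sequencing saturation in percent. Per the file headers, other columns hold segment area, run identifiers, quality flags and probe positions. Of 566 columns in the matrix, 417 matched a sample by name, and the 149 without a matching sample were not used.

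The matrix had 13906 gene targets and 1 negative-probe target, which is made of probes that match no human transcript and measures background. XIST and Y-linked targets (3) were left out, which left 13903. The total count per segment, after division by the factor, ran from 13939 to 7903905 with a median of 227851. A quality flag had been set by the authors on 237 segments, of which 228 were for a low negative-probe count, and 107 were for few nuclei or a small area. No segment was left out for these flags in the fits reported first. The depth limits low signals: in fallopian tube CD20 segments the third quartile was a median of 5 counts and 16.6% of targets sat at 1 count, so small differences in weakly expressed genes were not detectable there.

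The specimen was the replicate. Values were taken as log2(signal + 1), with a pseudocount of 1, and averaged over the segments of the same type in each specimen. A gene entered a comparison where its signal exceeded 2 times the negative-probe signal of the same segment in at least 10% of the segments. Comparisons were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes tested. Segment types were compared within specimens, with the specimen as a block. Sites were compared between specimens within a segment type, with the sequencing batch as a term; the batches matched the 2 sequencing runs, and fallopian tube specimens were in batch 2 only. Full ROI segments were all in batch 2, and the number shared by 1 omentum, 1 ovary and 1 fallopian tube specimen in the labels was read as a donor and used as a block. Tumor segments of ovary and omentum were compared in batch 1. In batch 1 each specimen had its own donor number, so site and donor cannot be told apart there. In batch 2 specimens of different sites shared donor numbers, which the main CD20 and Immune fits between sites did not take into account. The difference of CD20 and Immune segments was also compared between sites.

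For that pairing, expression profiles centred on the site mean were correlated across 10573 genes. The 12 pairs of Full ROI specimens with the same number had a median r of 0.32 and the 36 pairs with different numbers a median of -0.11, and 11 of 12 specimens had their highest correlation with a specimen of their own number. These are correlations across genes, which are not independent replicates. Deviations from a site mean cancel out within the site. A positive r within numbers therefore forces a negative average between them, so the -0.11 is not separate evidence.

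Gene lists (29) for cell types and pathways were written, and tests and alternatives fixed, before the data were examined. Lists with at least 4 genes tested were compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of each comparison. Unless stated otherwise, list medians are given relative to the median of all genes tested in the comparison, because that median depended on the scaling. Genes were named by a rule: the 8 largest changes in each direction among genes past the threshold that moved the same way in at least 80% of specimens, up to 4 members with the lowest p of each list described, the genes of the stained proteins, and, where fewer than 3 genes passed in a direction, the 3 with the lowest p. Some genes that met this rule are not reported here, and the counts of values of named genes include them. Counts of list members adjusted over the list alone stand beside the counts over all genes. Probe positions are those in the deposited probe table.

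The alternatives were a pseudocount of 5, no filter, a filter at 50% of segments, quantile normalisation, subtraction of the negative-probe signal, all segments in 1 fit with the specimen as a random block, edgeR 4.0.16 on the recovered counts, each batch alone, fits without the batch term or block, donor as a random block, regions holding both segment types, and each specimen left out in turn. Added after the data had been seen were fits without segments of few nuclei or small area, and without the 55 segments under 50000 counts. The procedure was tested on simulated data, with a specimen SD of 0.4 and a segment SD of 0.6 on the log2 scale and 200 genes changed by 1 or 2. For CD20 against Immune segments, with 11911 genes tested, it recovered 53.3% of genes changed by 1 and 100% of those changed by 2. For ovary against omentum CD20 segments, with 10552 genes tested, it recovered 7.7% and 60% of them. With all segments in 1 fit, 71.9% of calls between CD20 and Immune segments and 82% of calls between Tumor and Stroma segments were genes left unchanged in the simulation. The simulated data were noisier than the real data. The median SE was 0.183 against 0.126 for CD20 and Immune segments, and 0.25 against 0.145 for Tumor and Stroma segments. It was 0.315 against 0.235 for ovary and omentum CD20 segments. These shares therefore belong to the simulated setting and are not estimates for the data.

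Other splits of the specimens were counted, drawing 100 where there were more. Tests outside limma were exact permutation tests, or permutation tests with 100000 draws. Tables were made with data.table (version 1.17.8) and, in Python 3.11.15, with pandas 2.3.3 and NumPy 2.4.6; figures were drawn with matplotlib 3.10.9.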

Results

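The series measured RNA of 13903 gene targets in 417 stained segments from 20 specimens. Tumour-site specimens gave 78 CD20, 94 Immune, 76 Stroma, 41 Tumor, 105 Full ROI and 9 Other segments. By site, CD20 segments came from 6 omentum, 6 ovary and 4 fallopian tube specimens, and Immune segments from 5, 7 and 4. Stroma segments came from 6 omentum and 4 ovary specimens, and Full ROI segments from 4 specimens of each site. The lymph node control gave 5 CD20, 4 Immune and 5 Stroma segments from 1 specimen. The total count per segment had a median of 110357 in CD20 segments (13939 to 1877579) and 139189 in Immune segments (14710 to 1135737). It was 361529 in Stroma segments (16076 to 3575948), 557764 in Tumor segments (14297 to 6862147) and 265441 in Full ROI segments (30116 to 4224546). The series title names its subject as tertiary lymphoid structures, the lymphoid aggregates that form outside lymphoid organs, and asks how site and stroma bear on them.

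CD20 segments were compared with Immune segments of the same 15 specimens, which asks what sets apart B cell areas from the other leukocyte areas. Genes of B cells were higher in CD20 segments in 13 of 15 specimens: the mean of the 13-gene list differed by 0.38 ± 0.48 (SD, n = 15) on the log2 scale. CD79A, the signalling partner of the B cell receptor, was at 4.87 ± 0.66 against 4.12 ± 0.62 and higher in 13 of 15 specimens. VPREB3, a B-lineage gene, was at 4.14 ± 0.60 against 3.56 ± 0.40, and TNFRSF13C, the receptor for the B cell survival factor BAFF, was at 4.24 ± 0.68 against 3.64 ± 0.47. Genes of follicular dendritic cells, the stromal cells of B cell follicles, had higher values too: FDCSP was at 4.34 ± 0.94 against 3.62 ± 0.75, CR2 at 4.12 ± 0.77 against 3.74 ± 0.57, and CXCL13, which attracts B cells, at 5.05 ± 1.35 against 4.44 ± 1.05. The list of follicular dendritic and reticular cells was higher in 10 of 15 specimens. In its CD20 values 1 ovary specimen was at 5.12 and the other ovary specimens at 3.72 to 3.97. Genes of cytotoxic lymphocytes had lower values, with CD8A at 3.47 ± 0.47 against 4.03 ± 0.44 and CCL5 at 4.07 ± 0.60 against 4.64 ± 0.47, lower in 14 of 15 specimens.

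None of these genes passed the test over all genes. Limma called 0 of 9263 genes; 455 had an unadjusted p under 0.05, and edgeR on recovered counts called 90, of which 39 were higher in CD20 segments. The lowest adjusted p was 0.139, for CD79A (log2 difference 0.76, SE 0.15), whose probe lies on chromosome 19 from 41880732 to 41880899 on GRCh38.p13. When adjusted over the list alone, 7 of 13 B cell genes and 3 of 11 follicular dendritic and reticular cell genes were higher, and 3 of 9 cytotoxic lymphocyte genes were lower. With the preset correlation, the lists of B cells (median 0.36 above that of all genes, adjusted p = 2.71e-12), follicular dendritic and reticular cells (0.13, adjusted p = 0.000168) and germinal centre genes (0.25, adjusted p = 0.00787) were higher. The lists of cytotoxic lymphocytes (-0.26, adjusted p = 1.65e-09), T cells (-0.20, adjusted p = 1.7e-06), macrophages (-0.30, adjusted p = 1.01e-07) and plasma cells (-0.14, adjusted p = 0.00435) were lower. None of the 9 lists called in this way held with an estimated correlation: the B cell, cytotoxic and T cell lists had an adjusted p = 0.0936 with an estimated correlation, the macrophage list 0.118, the follicular dendritic and germinal centre lists 0.165 and the plasma cell list 0.208. Among ovary CD20 segments the highest specimen stood apart in T cell genes (4.75, others at most 3.83) and macrophage genes (4.85, others at most 4.03). Among ovary Immune segments it did so in plasma cell genes (6.48, others at most 4.68). The B cell list differed by 0.59 ± 0.51 (SD, n = 7) in batch 1 and by 0.20 ± 0.39 (SD, n = 8) in batch 2, and its call ended in batch 2 alone (adjusted p = 0.108), where the plasma cell list turned to 0.092. MS4A1 encodes the stained CD20 itself and PTPRC encodes CD45, so their values (0.76, SE 0.18, and 0.016, SE 0.13) describe how the segments were chosen.

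Tumor segments were compared with Stroma segments of the same 8 specimens. Carcinoma genes were higher in Tumor segments: 17 of 18 listed epithelial genes rose and 0 fell, and the list mean was 4.80 ± 0.58 against 3.60 ± 0.15 (SD, n = 8), higher in 8 of 8 specimens. The largest rises included WFDC2, which encodes the ovarian carcinoma marker HE4 (log2 difference 1.91, SE 0.29), the laminin receptor BCAM (1.80, SE 0.31) and the laminin chain LAMA5 (1.75, SE 0.14, adjusted p = 1.97e-05). The tight junction genes CLDN4 (1.64, SE 0.17) and CLDN3 (1.35, SE 0.15), the adhesion genes CDH1 (1.21, SE 0.13) and EPCAM (1.10, SE 0.14), and LAPTM4B, SLPI and SLC34A2 (1.69, 1.69 and 1.63) rose as well. KRT8, KRT18 and KRT19 encode stained cytokeratins, so their rises of 1.59, 1.57 and 1.11 follow from the choice of segments. The epithelial list holds these genes and the stain picks epithelial cells, so the rise of the list is in part built in.

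Fibroblast genes fell furthest: 14 of 14 were lower, with list means of 3.89 ± 0.81 in Tumor and 5.95 ± 1.17 in Stroma segments (SD, n = 8), lower in 8 of 8 specimens. The collagen genes COL1A2 (-3.58, SE 0.36, adjusted p = 0.00013), COL1A1 (-3.49, SE 0.36) and COL3A1 (-3.23, SE 0.39) and the proteoglycan gene DCN (-2.58, SE 0.27) were among them. Of 12 genes of TGF-beta signalling and matrix, 11 fell, SPARC by 2.70 (SE 0.33) and VCAN by 1.92 (SE 0.30) on the log2 scale. Antibody genes fell with them: IGHG1, IGHG2, IGHG3 and IGHG4, close paralogs, differed by -3.21, -3.09, -3.26 and -3.03, IGKC by -2.92 (SE 0.51) and JCHAIN by -1.53 (SE 0.35). Of 10 macrophage genes 9 fell, among them the complement C1q genes C1QA (-1.37, SE 0.22) and C1QC (-1.61, SE 0.27) and the lysozyme gene LYZ (-1.04, SE 0.19). Of 5 smooth muscle genes 3 fell (TAGLN, MYLK by 0.91 and ACTG2 by 0.84), as did 3 of 9 complement genes (C1S by 1.37 and C1R by 1.09 among them). Of genes of cell division and low oxygen, 2 of 12 proliferation genes rose, UBE2C (0.93, SE 0.21) and CDK1 (0.45, SE 0.14), and 2 of 6 hypoxia genes, SLC2A1 (0.84, SE 0.21) and BNIP3 (0.58, SE 0.18).

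Limma called 1026 of 6763 genes, 745 higher and 281 lower in Tumor segments. That split differed under other processing: quantile normalisation gave 462 higher and 546 lower, background subtraction 28 and 152, and edgeR, which also changes the test, 1145 and 1465. The median of all genes was 0.13 and shifted by -0.101 under quantile normalisation and by -0.144 in edgeR. Relative to it, the medians were 1.03 for carcinoma epithelium, -1.94 for fibroblasts, -1.43 for TGF-beta and matrix, -0.97 for smooth muscle, -0.76 for plasma cells and -0.73 for complement. These 6 lists held with an estimated correlation (adjusted p = 0.0399 for each). The macrophage list (-1.03) did not (adjusted p = 0.0706 with an estimated correlation), nor did hypoxia (0.44) and proliferation (0.18; adjusted p = 0.319 with an estimated correlation for both). In omentum Tumor segments, 1 of 5 specimens stood apart in hypoxia genes (6.35 against at most 4.59) and 1 in plasma cell genes (5.68 against at most 4.31). Adjusted over the list alone, 18 of 18 carcinoma, 4 of 12 proliferation and 3 of 6 hypoxia genes were higher. So adjusted, 14 of 14 fibroblast, 12 of 12 matrix, 9 of 10 macrophage, 6 of 9 plasma cell, 4 of 5 smooth muscle and 3 of 9 complement genes were lower. Leaving out 1 specimen at a time moved the count between 567 and 1907, and without the specimen as a block it was 483.

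**Figure D1:**
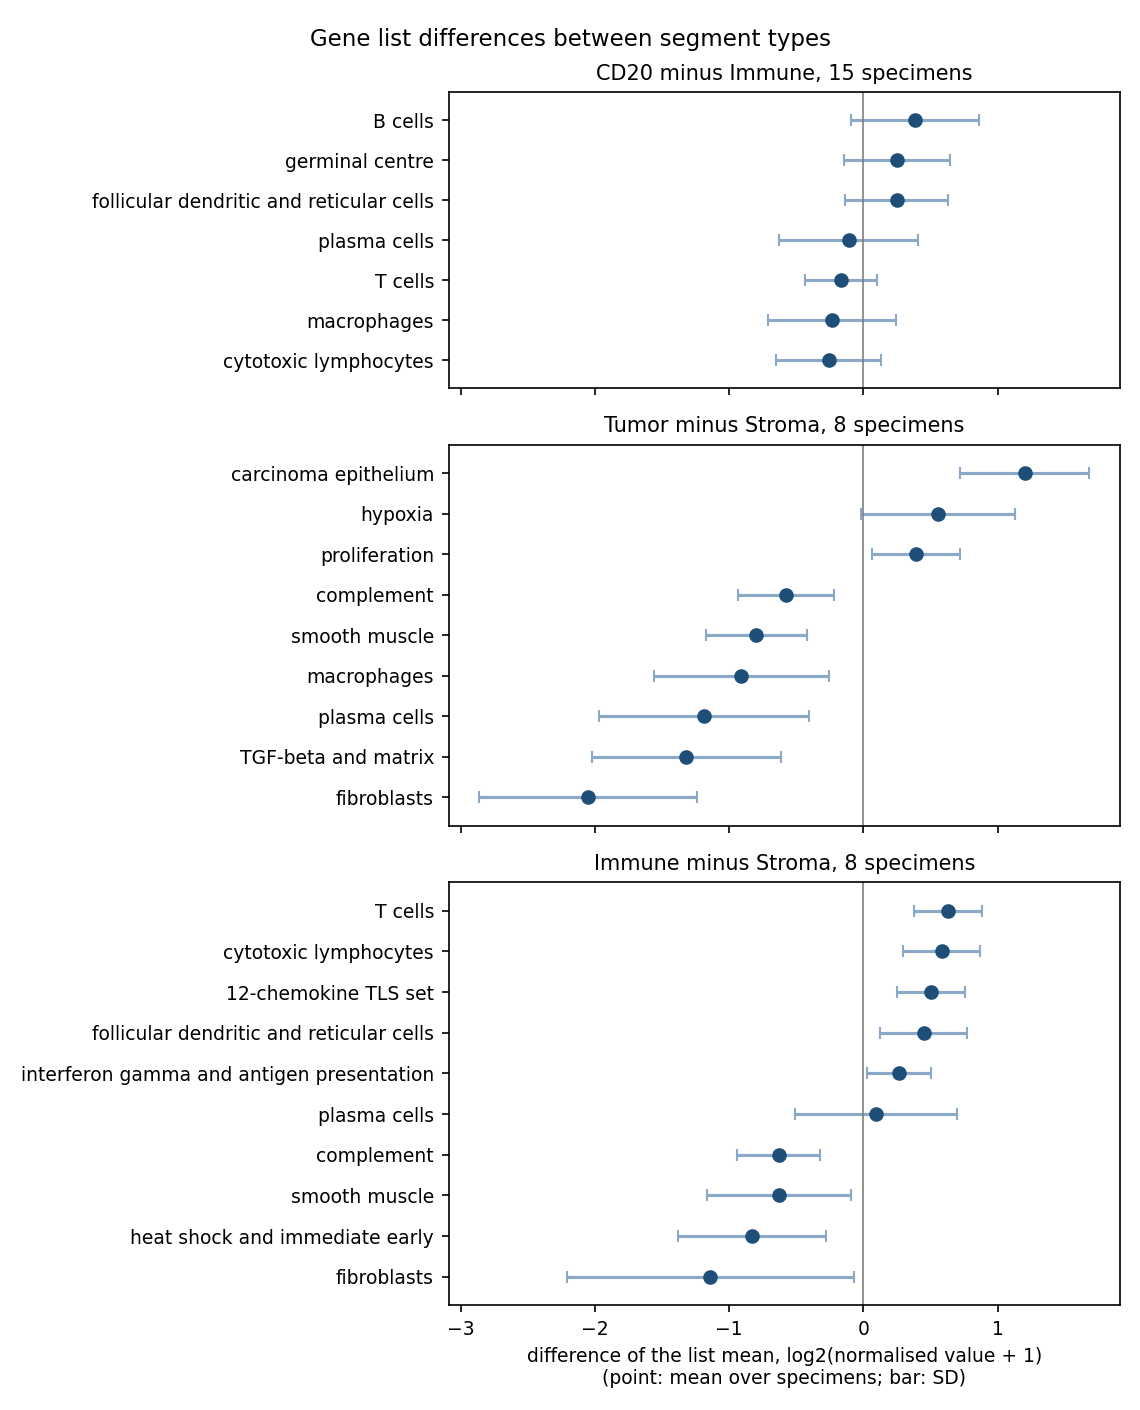
The points give the mean over specimens, and the bars the SD, of the difference of each list mean on the log2(normalised value + 1) scale, for the 3 comparisons between segment types (15, 8 and 8 specimens). Carcinoma epithelium (1.20 ± 0.48) and fibroblasts (-2.05 ± 0.81) lie farthest apart between Tumor and Stroma, and the B cell list lies at 0.38 ± 0.48 between CD20 and Immune.

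Immune segments were compared with Stroma segments of the same 8 specimens. T cell genes rose: 7 of 9 were higher and 0 lower, with a list mean of 4.22 ± 0.26 against 3.59 ± 0.11 (SD, n = 8), higher in 8 of 8 specimens. TRBC1 and TRAC, constant chains of the T cell receptor, rose by 1.34 (SE 0.21) and 1.11 (SE 0.16), CD3E by 1.06 (SE 0.14, adjusted p = 1.34e-05), CD3D by 0.69 (SE 0.14) and the interleukin-7 receptor gene IL7R by 0.91 (SE 0.14). Of 8 cytotoxic lymphocyte genes 5 rose, including CCL5 (1.06, SE 0.15), CD8A (0.81, SE 0.17) and NKG7 (0.74, SE 0.15). Chemokine genes that mark lymphoid aggregates rose in part: 3 of 6 genes measured from a 12-gene set, among them CCL19, which attracts T cells and dendritic cells (1.23, SE 0.30), and CXCL9, induced by interferon gamma (0.83, SE 0.20). The leukocyte genes LCP1 and PTPRCAP rose by 1.03 and 1.12, and LTB, a cytokine gene of lymphoid tissue, by 0.94 (SE 0.19). Of 11 genes of interferon gamma and antigen presentation 1 rose, and GBP5 was at 0.44 (SE 0.15, adjusted p = 0.0677). Of 12 plasma cell genes 1 rose, CD38 (0.49, SE 0.14).

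Among the largest falls in Immune segments were AEBP1 (-1.86, SE 0.30), DCN (-1.71, SE 0.24), COL6A1 (-1.63, SE 0.23), TIMP2 (-1.62, SE 0.22), THBS2 (-1.56, SE 0.28) and COL5A2, genes of collagens and other matrix proteins. Of 14 fibroblast genes 5 fell, ACTA2 by 1.47 (SE 0.19) and PDGFRA by 0.62 (SE 0.13), and the list had an adjusted p = 0.0731 with an estimated correlation. Of 9 complement genes 5 fell, among them C1R and C1S (-1.14 and -1.15), and 3 of 5 smooth muscle genes fell, TAGLN by 1.20 and MYLK by 0.85 (adjusted p = 0.164 for the list with an estimated correlation). The immediate early genes EGR1, FOS and JUN, which respond within minutes to stimuli and to tissue handling, fell by 1.68, 1.49 and 0.72. PTPRC (0.89, SE 0.14), KRT8 (-1.01, SE 0.14) and KRT18 (-0.70, SE 0.17) encode stained proteins and are not findings, and MS4A1 was at 0.30 (SE 0.15, adjusted p = 0.25).

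Limma called 416 of 5904 genes, 86 higher and 330 lower. Background subtraction gave 18 higher and 949 lower and moved the median of all genes, -0.078, by -0.656; edgeR gave 306 higher and 428 lower. Relative to that median, T cells (0.64), cytotoxic lymphocytes (0.60) and the chemokine set (0.72) held with an estimated correlation (adjusted p = 0.0266), as did follicular dendritic and reticular cells (0.34, adjusted p = 0.033), interferon gamma and antigen presentation (0.32, adjusted p = 0.0484) and complement (-0.46, adjusted p = 0.0479). Fibroblasts (-1.08) and heat shock and immediate early genes (-0.49) had an adjusted p = 0.0731 with an estimated correlation, smooth muscle (-0.44) 0.164 and plasma cells (0.24) 0.45. Adjusted over the list alone, 8 of 9 T cell, 7 of 8 cytotoxic, 4 of 6 chemokine, 3 of 7 follicular dendritic, 3 of 11 interferon and 2 of 12 plasma cell genes were higher. So adjusted, 10 of 14 fibroblast, 7 of 9 complement, 6 of 6 heat shock and immediate early, 4 of 5 smooth muscle and 1 of 6 chemokine genes were lower. Leaving out 1 specimen at a time moved the count between 252 and 706, and without the specimen as a block it was 155.

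Ovary CD20 segments (6 specimens) were compared with omentum CD20 segments (6 specimens) to ask whether B cell areas differed by site. B cell genes had lower values in ovary, with a list mean of 3.97 ± 0.48 against 4.43 ± 0.30 (SD, n = 6 each), as did genes of follicular dendritic and reticular cells, at 4.06 ± 0.51 (1 specimen at 5.08, the other 5 at 3.74 to 4.03) against 4.47 ± 0.23. CD79A was at 4.66 ± 0.84 against 5.47 ± 0.37, FDCSP at 4.08 ± 0.54 against 5.39 ± 0.77 and CR2, the complement receptor of B cells and follicular dendritic cells, at 3.94 ± 0.49 against 4.97 ± 0.57. The linker histone gene H1-4 (4.84 ± 0.52 against 6.57 ± 0.43), the actin nucleation gene ACTR3 (4.12 ± 0.13 against 5.32 ± 0.33) and the ribosomal gene RPSA (5.78 ± 0.55 against 7.38 ± 0.57) had the lowest p among lower genes. FAM20C, OSGIN1 and FAH had the lowest p among higher genes (log2 differences 0.77, 0.74 and 0.76), and none passed.

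No gene of 9038 passed in limma (0 calls); 816 had an unadjusted p under 0.05 and edgeR called 9. The lists of B cells (-0.67 relative to all genes, adjusted p = 2.64e-07) and follicular dendritic and reticular cells (-0.45, adjusted p = 0.000278) were lower with the preset correlation, and both had an adjusted p = 0.566 with an estimated correlation. Of these genes, 0 of 13 and 3 of 10 were lower when adjusted over the list alone. The median of all genes was 0.14 and moved by -0.183 under quantile normalisation, by -0.858 under background subtraction and by -0.109 in edgeR. In ovary, 22 of 36 CD20 segments were marked for few nuclei or a small area and the median negative-probe signal was 9.45, against 10 of 35 and 7.17 in omentum. Leaving out 1 ovary specimen gave 116 calls, and a filter at 50% of segments gave 22. Without segments under 50000 counts the B cell list mean differed by -0.83 (SE 0.21), against -0.49 (SE 0.24) with all segments.

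Fallopian tube CD20 segments (4 specimens) were compared with those of omentum and ovary. B cell genes had lower values in fallopian tube than in omentum, at a list mean of 3.75 ± 0.53 (SD, n = 4) against 4.43 ± 0.30 (SD, n = 6). FDCSP, a gene of follicular dendritic cells, was at 3.52 ± 0.42 against 5.39 ± 0.77 and HLA-DOB, an antigen-presentation gene of B cells, at 3.46 ± 0.42 against 4.24 ± 0.47. These means hold no batch term, and with it FDCSP differed by -1.77 (SE 0.423, adjusted p = 0.8). Complement genes had higher values in fallopian tube, at 5.09 ± 0.53 against 4.32 ± 0.32 in omentum (1 specimen at 4.92, the others at 3.99 to 4.34) and 4.26 ± 0.59 in ovary, with C4B at 5.81 ± 0.45 against 4.08 ± 0.60 and 4.18 ± 0.48 and CFB at 4.95 ± 1.39 against 3.47 ± 0.18 in omentum. Fibroblast genes were at 5.22 ± 0.62 against 4.46 ± 0.62 and 4.33 ± 0.57, with DCN at 6.11 ± 0.73 against 4.71 ± 0.36 and 4.27 ± 0.81. Macrophage genes were at 4.19 ± 0.63 against 3.94 ± 0.21 in omentum, with CD163 at 4.50 ± 0.75 against 3.65 ± 0.35 and LYZ at 5.90 ± 1.07 against 4.80 ± 0.33. Against ovary, proliferation genes were at 3.40 ± 0.54 against 3.81 ± 0.24 (1 fallopian tube specimen at 4.20, the others at 3.04 to 3.22), with MKI67 at 3.11 ± 0.56 against 3.74 ± 0.21 and MCM2 at 3.03 ± 0.74 against 4.06 ± 0.45. PHLDA1 and CCNL1 (1.03 and 1.14 against omentum) and TXNIP, CAPZB and SYNGR2 (2.00, 1.46 and 1.40 against ovary) had the lowest p among other higher genes. PTPN18 (-1.12 against omentum) and WNT8A, ZIM3 and BRME1 (-1.28, -1.16 and -1.06 against ovary) had it among lower ones. The median negative-probe signal was 7.06 in fallopian tube and 9.45 in ovary CD20 segments. Lower values of proliferation genes and other weak genes than in ovary thus cannot be told apart from background.

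In both comparisons limma called 0 of 9038 genes, and 9 and 7 of 26 lists were called with the preset correlation, not all of them given here; 399 and 893 had an unadjusted p under 0.05, and edgeR called 53 and 15. Against omentum, the lists of B cells (-0.76 relative to all genes, adjusted p = 3.58e-09), complement (0.63, adjusted p = 1.92e-05), fibroblasts (0.46, adjusted p = 1.07e-05) and macrophages (0.42, adjusted p = 0.000413) were called with the preset correlation, and each had an adjusted p = 0.362 with an estimated correlation. Against ovary, complement (0.90, adjusted p = 4.03e-07) and fibroblasts (1.14, adjusted p = 5.72e-09) also had 0.362, and proliferation (-0.24, adjusted p = 0.0343) had 0.832. When adjusted over the list alone, 5 of 13 B cell genes were lower and 2 of 9 complement genes higher than in omentum, and 1 of 9 complement and 1 of 13 fibroblast genes were higher and 2 of 11 proliferation genes lower than in ovary. Leaving out 1 fallopian tube specimen gave up to 460 calls against ovary. In edgeR the fibroblast list turned to -0.154 against ovary, and COL1A1 (1.52) turned to -0.353 against omentum and COL3A1 (1.75) to -0.358 against ovary. Fallopian tube was in batch 2 only and gave 7 CD20 segments with a median total count of 60132, against 134550 in omentum and 99656 in ovary. The median of all genes was -0.065 and -0.189 and moved in the latter by 0.199 under quantile normalisation, 0.547 under background subtraction and 0.185 in edgeR.

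**Figure D2:**
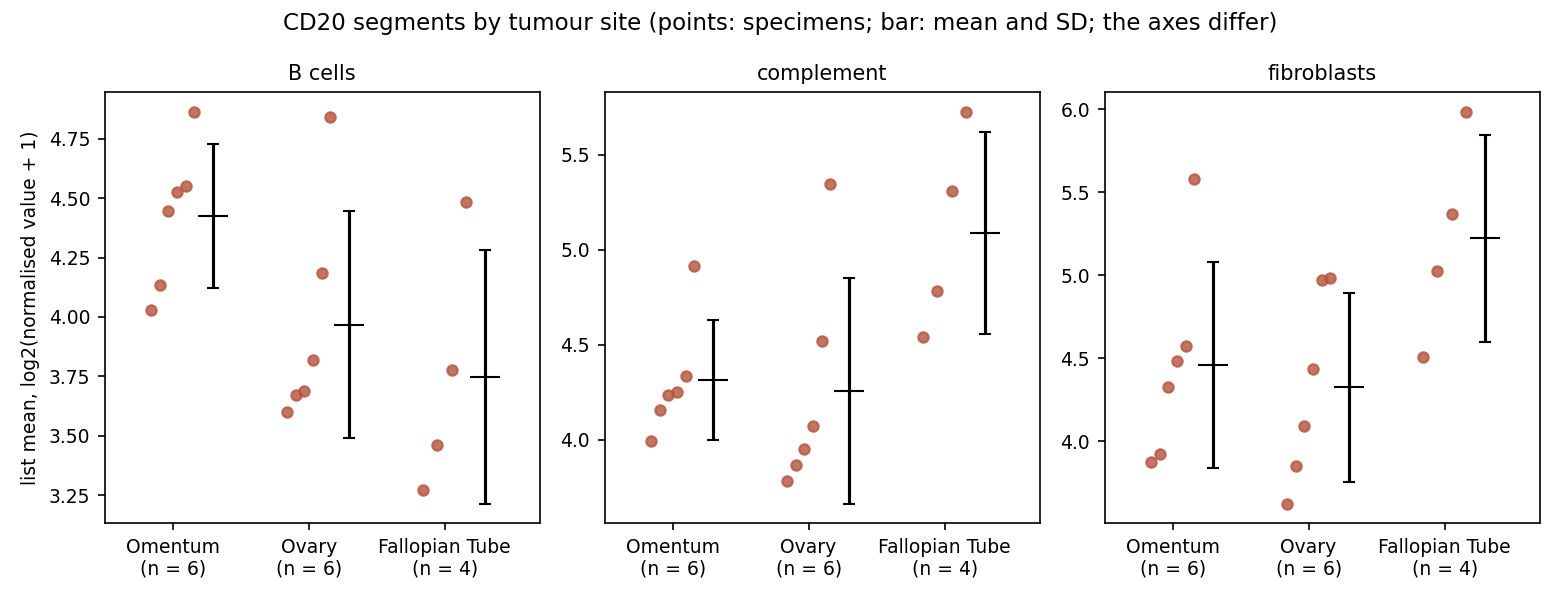
Each point is 1 specimen's mean of the list in its CD20 segments on the log2(normalised value + 1) scale, and the black bars give the mean and SD of 6 omentum, 6 ovary and 4 fallopian tube specimens. The B cell means are 4.43, 3.97 and 3.75, and the complement means 4.32, 4.26 and 5.09.

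Immune segments were compared between 7 ovary, 5 omentum and 4 fallopian tube specimens. T cell genes were at 3.99 ± 0.27 in ovary and 4.23 ± 0.22 in omentum, with TRAC at 4.61 ± 0.61 against 5.19 ± 0.36 and IL7R at 4.31 ± 0.78 against 4.85 ± 0.19. SFRP2, a secreted Wnt modulator of fibroblasts, was at 3.70 ± 0.41 in ovary and 4.83 ± 0.92 in omentum, and CD164, a sialomucin, at 3.64 ± 0.28 against 4.46 ± 0.40. Complement genes were at 4.96 ± 0.49 in fallopian tube, 4.29 ± 0.48 in ovary and 4.29 ± 0.21 in omentum, with C4B at 5.05 ± 0.49 against 4.16 ± 0.58 in ovary. Macrophage genes were at 4.61 ± 0.44 in fallopian tube and 4.12 ± 0.26 in omentum, smooth muscle genes at 3.82 ± 0.80 and 3.38 ± 0.36, and FDCSP at 2.82 ± 0.40 and 4.32 ± 0.31. These means hold no batch term, and fallopian tube was in batch 2 only; with the batch term FDCSP differed by -1.09 (SE 0.285, adjusted p = 0.83). DCN was at 6.04 ± 0.93 in fallopian tube and 4.70 ± 0.93 in ovary.

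In each of these 3 comparisons limma called 0 of 10707 genes. For ovary against omentum, fallopian tube against omentum and fallopian tube against ovary, 277, 207 and 250 genes had an unadjusted p under 0.05, and edgeR called 0, 0 and 1. With the preset correlation 3, 6 and 6 of 27 lists were called, not all of them given here: ovary differed from omentum in T cells (-0.21), smooth muscle (0.31) and ovarian stroma genes (0.28), each with adjusted p = 0.0307 and with 0.95 under an estimated correlation. Fallopian tube differed from omentum in smooth muscle (0.49, adjusted p = 5.4e-05), macrophages (0.52, adjusted p = 0.000482), complement (0.34, adjusted p = 0.00106) and B cells (-0.18, adjusted p = 0.0193); with an estimated correlation these had an adjusted p = 0.574, and B cells 0.722. It differed from ovary in complement (0.56, adjusted p = 1.36e-06; 0.146 with an estimated correlation), TGF-beta and matrix (0.27) and fibroblasts (0.26, both adjusted p = 0.00497; 0.867 with an estimated correlation). When adjusted over the list alone, 1 of 11 TGF-beta and matrix genes was higher than in ovary and 0 members of the other lists named here passed. In edgeR the macrophage list of fallopian tube turned to -0.03 against omentum. Its complement list ran from -0.015 to 0.613 with 1 specimen left out. The smooth muscle list of ovary was -0.009 against omentum without small segments. In complement genes 1 omentum specimen was at 4.66 and the others at 4.12 to 4.24. In B cell genes 1 fallopian tube specimen was at 3.25 and the others at 3.74 to 3.78.

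Full ROI segments, which the labels do not tie to a stain, were compared between 4 specimens of each site that shared donor numbers. Smooth muscle genes had lower values in omentum, at a list mean of 3.21 ± 0.28 against 3.76 ± 0.45 in ovary and 4.13 ± 0.82 in fallopian tube (SD, n = 4 each), where 1 specimen was at 2.90 and the other 3 at 4.50 to 4.58. MYH11, the smooth muscle myosin gene, was at 4.29 ± 1.03 in fallopian tube against 2.93 ± 0.24, ACTG2 at 3.83 ± 0.64 against 2.79 ± 0.37, and DES at 3.72 ± 0.82 against 2.89 ± 0.52. Genes of interferon gamma and antigen presentation had higher values in omentum (4.74 ± 0.61) than in ovary (4.32 ± 0.25) and fallopian tube (4.26 ± 0.15). IRF1 was at 4.47 ± 0.50 in omentum and 3.89 ± 0.26 in fallopian tube. Plasma cell genes were at 4.71 ± 1.05 in omentum, 4.24 ± 0.38 in ovary and 4.06 ± 0.51 in fallopian tube, with IGKC at 7.54 ± 3.14, 6.21 ± 1.39 and 5.55 ± 2.02. Heat shock and immediate early genes were highest in ovary, at 5.37 ± 0.50 against 4.66 ± 0.29 in omentum and 5.00 ± 0.43 in fallopian tube, with HSPA1B at 4.78 ± 1.07, 3.47 ± 0.64 and 3.97 ± 0.36. IGFBP5, which binds insulin-like growth factors, was at 6.19 ± 0.90 in ovary against 4.03 ± 0.47 in omentum (adjusted p = 0.255), and the detoxification gene EPHX1 at 4.96 ± 0.49 against 3.88 ± 0.27 and, in fallopian tube, 4.04 ± 0.34. Against ovary, fallopian tube also had hypoxia genes at 4.25 ± 0.38 against 3.98 ± 0.17 and complement genes at 4.63 ± 0.24 against 4.99 ± 0.39.

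Limma called 0 of 10573 genes in each comparison. For ovary against omentum, fallopian tube against omentum and fallopian tube against ovary, 586, 324 and 316 genes had an unadjusted p under 0.05, and edgeR called 0 in each. With the preset correlation 12, 7 and 4 of 25 lists were called, not all of them given here, and 0 with an estimated correlation. Ovary against omentum gave heat shock and immediate early (0.69, adjusted p = 5.73e-06; 0.247 with an estimated correlation), smooth muscle (0.59, adjusted p = 9.5e-05; 0.532), interferon gamma and antigen presentation (-0.46, adjusted p = 1.02e-08; 0.313) and plasma cells (-0.39, adjusted p = 6.78e-06; 0.313). Fallopian tube against omentum gave smooth muscle (0.77, adjusted p = 1.05e-13), interferon gamma and antigen presentation (-0.47, adjusted p = 4.54e-13) and plasma cells (-0.57, adjusted p = 2.94e-10), each with an adjusted p = 0.167 with an estimated correlation. Fallopian tube against ovary gave hypoxia (0.31, adjusted p = 0.000929; 0.464 with an estimated correlation), complement (-0.45, adjusted p = 0.00184; 0.934) and heat shock and immediate early (-0.38, adjusted p = 0.00184; 0.464). When adjusted over the list alone, 7 of 7 smooth muscle genes were higher and 1 of 13 interferon genes lower in fallopian tube than in omentum, 3 of 8 heat shock and immediate early genes were higher in ovary than in omentum, and 0 members of the other lists named here passed.

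Stroma segments were compared between 4 ovary and 6 omentum specimens. Fibroblast genes had lower values in ovary stroma, at a list mean of 4.76 ± 0.36 (SD, n = 4) against 6.70 ± 0.82 (SD, n = 6). COL3A1 was at 6.06 ± 1.57 against 9.34 ± 0.60, the proteoglycan gene LUM at 4.67 ± 0.86 against 7.28 ± 0.97, and SFRP2 at 3.77 ± 0.48 against 6.38 ± 1.44. Genes of TGF-beta signalling and matrix were at 4.11 ± 0.36 against 5.41 ± 0.57, with CTHRC1 at 3.71 ± 0.37 against 6.01 ± 1.60, VCAN at 4.10 ± 0.46 against 5.85 ± 0.72 and TGFBI at 3.50 ± 0.33 against 4.71 ± 0.84. Macrophage genes were at 4.03 ± 0.43 against 4.59 ± 0.48, with FCGR3A at 4.06 ± 0.26 against 4.74 ± 0.66 and CD68 at 3.90 ± 0.42 against 4.54 ± 0.55. Genes of ovarian stroma and steroidogenesis had higher values in ovary, at 4.00 ± 0.23 against 3.50 ± 0.29, with NR5A1, the transcription factor SF-1, at 3.98 ± 0.21 against 3.47 ± 0.19, GATA4 at 4.05 ± 0.48 against 3.36 ± 0.41 and the inhibin gene INHA at 3.97 ± 0.30 against 3.50 ± 0.26. The median negative-probe signal was 9.5 in ovary and 8.24 in omentum Stroma segments. In lymph node Stroma segments 4 genes of the ovarian stroma list were at 3.92. The higher values of this list in ovary thus cannot be told apart from background. KLHDC8A and HS3ST1 (0.97 and 0.80) were the other higher genes with the lowest p, and neither passed.

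Limma called 3 of 5741 genes, all lower in ovary stroma; 658 had an unadjusted p under 0.05 and edgeR called 0. They were NNMT, nicotinamide N-methyltransferase (-2.13, SE 0.35), whose probe lies on chromosome 11 from 114312353 to 114312402, CCDC80, a secreted matrix protein gene (-1.58, SE 0.27; chromosome 3, 112607212 to 112609982) and the membrane protein gene EMP1 (-1.15, SE 0.20; chromosome 12, 13216000 to 13216049). Each had an adjusted p = 0.0479, and each lost its call with a pseudocount of 5 (adjusted p = 0.0701) and without the batch term (0.291); leaving out 1 specimen at a time gave 0 to 92 calls. With the preset correlation 7 of 17 lists were called; of these, fibroblasts (-2.04 relative to all genes, adjusted p = 2.5e-13) and TGF-beta and matrix (-1.13, adjusted p = 2.13e-10) were lower, both with an adjusted p = 0.158 with an estimated correlation. Macrophages (-0.54, adjusted p = 7.22e-05) had 0.324 and ovarian stroma and steroidogenesis (0.54, adjusted p = 5.52e-05) had 0.215. Adjusted over the list alone, 12 of 14 fibroblast and 8 of 12 TGF-beta and matrix genes were lower, 3 of 4 ovarian stroma genes were higher, and 0 of 11 macrophage genes passed. Within batch 1 the fibroblast list mean differed by -1.51 (SE 0.45), against -1.90 (SE 0.42) over both batches; batch 2 held 1 ovary specimen with Stroma segments. The median of all genes was -0.036 and moved by -0.399 under background subtraction.

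**Figure D3:**
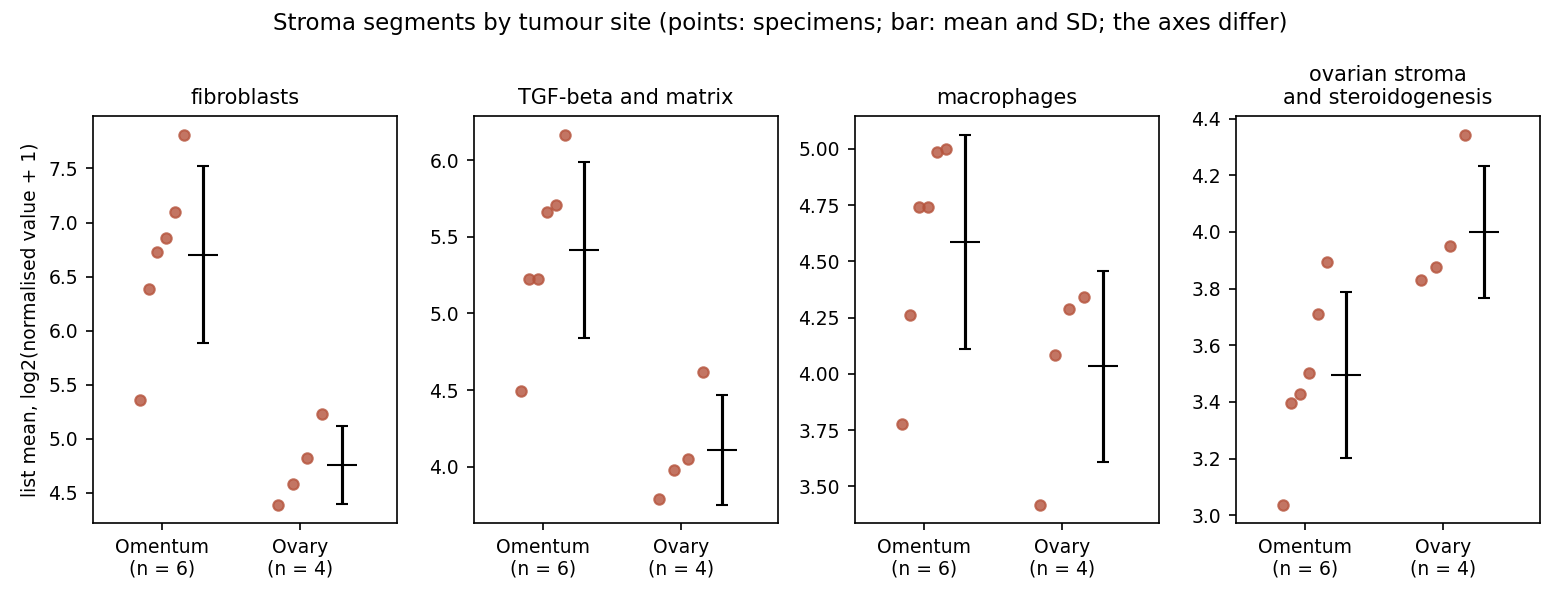
Each point is 1 specimen's mean of the list in its Stroma segments on the log2(normalised value + 1) scale, and the black bars give the mean and SD of 6 omentum and 4 ovary specimens. The fibroblast means are 6.70 and 4.76, and the 4 ovary values lie below those of all 6 omentum specimens. The ovarian stroma means are 3.50 and 4.00, a difference that cannot be told apart from background.

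Tumor segments were compared between 3 ovary and 4 omentum specimens of batch 1. EMP1 was at 2.91 ± 0.20 in ovary (SD, n = 3) and 5.16 ± 0.75 in omentum (SD, n = 4), LCP1, an actin-bundling gene of leukocytes, at 2.95 ± 0.42 and 4.68 ± 0.57, and COL3A1 at 3.79 ± 0.52 and 5.51 ± 0.95. The metallothionein genes MT1G (5.70 ± 0.89 against 4.02 ± 0.26) and MT1M (4.94 ± 0.85 against 3.64 ± 0.27) had higher values in ovary. Limma called 0 of 8179 genes; 226 had an unadjusted p under 0.05, and edgeR called 0. Fibroblast genes were at 3.60 ± 0.36 against 4.35 ± 0.72 (-0.73 relative to all genes, adjusted p = 1.04e-07; 0.705 with an estimated correlation), and 2 of 9 were lower when adjusted over the list alone. In all, 3 of 14 lists were called with the preset correlation.

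The difference between CD20 and Immune segments was then compared between sites. For B cell genes it was 0.68 ± 0.54 (SD, n = 5) in omentum, 0.32 ± 0.38 (SD, n = 6) in ovary and 0.12 ± 0.45 (SD, n = 4) in fallopian tube. For CD79A, a signalling chain of the B cell receptor, and CD22, an inhibitory co-receptor of B cells, the difference over both batches was 1.32 ± 0.65 and 0.86 ± 0.51 in omentum and 0.55 ± 0.54 and 0.16 ± 0.32 in ovary. Limma called 0 of 9263 genes for ovary against omentum and 0 for fallopian tube against omentum; 203 and 163 had an unadjusted p under 0.05, and edgeR called 0 and 1. The B cell list differed by -0.35 in ovary relative to all genes (adjusted p = 0.000389; 0.933 with an estimated correlation), and 0 of 13 members passed when adjusted over the list alone; no list passed for fallopian tube.

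Lists for the lymph node control used members past the filter in the pooled CD20, Immune and Stroma segments of tumour-site specimens of batch 1. That control had 1 specimen and so no replicate. B cell genes were at 5.12 in its CD20 segments, against 3.69 to 4.95 in CD20 segments of the 7 tumour-site specimens of batch 1, and T cell genes at 4.95 in its Immune segments against 3.93 to 4.73. Its Stroma segments had fibroblast genes at 3.41 against 4.39 to 6.85. The difference of CD20 and Immune segments in B cell genes was 1.30, inside the range of 0.051 to 1.43 in tumour-site specimens. The median total count of its CD20 segments was 4262895, against 117936 in those of the 7 specimens.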

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

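The tests of depth, batch, site and cell composition described here were chosen after the results they measure had been seen; the comparisons with random gene lists were not.

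Of 162 groups of specimens examined for a value far from the rest, 19 had a gap that was large against the range of the group, where chance gives about 5%. In CD20 segments, 1 ovary specimen stood above the other 5 in follicular dendritic and reticular cell genes (5.12 against at most 3.97; the gap was 0.825 of the range), macrophage genes (4.85 against 4.03; 0.828) and T cell genes (4.75 against 3.83; 0.688). The follicular dendritic list gave 0.783 over the genes tested between sites. In omentum CD20 segments, 1 specimen was high in germinal centre genes (4.04 against 3.52; 0.827) and 1 in complement genes (4.92 against 4.34; 0.629). In fallopian tube CD20 segments, 1 specimen was high in proliferation genes (4.20 against 3.22; 0.844). In Immune segments, the lowest fallopian tube specimen had B cell genes at 3.25 against 3.74 to 3.78 (0.918, in the comparison of segment types and in that of sites). Ovary Immune segments had 1 specimen high in germinal centre genes (3.93 against 3.36; 0.632) and 1 in plasma cell genes (6.48 against 4.68; 0.761), and omentum Immune segments 1 high in complement genes (4.66 against 4.24; 0.773).

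In Full ROI segments of fallopian tube, 1 specimen had smooth muscle genes at 2.90, against 4.50 to 4.58 in the other 3 (0.952). Hypoxia genes were high in 1 omentum specimen in Stroma segments (4.56 against 4.08; 0.801) and in 1 in Tumor segments (6.35 against 4.59; 0.729). Plasma cell genes were high in the Tumor segments of 1 omentum specimen (5.68 against 4.31; 0.771), and proliferation genes were low in the Stroma segments of 1 (3.29 against 3.55; 0.719). For the difference of CD20 and Immune segments, adipocyte genes were low in 1 omentum specimen (-0.88 against -0.14; 0.812) and high in 1 ovary specimen (1.22 against 0.40; 0.641). That difference also differed between ovary and omentum for 3 lists by a test of the difference itself: B cells (-0.35 relative to all genes, adjusted p = 0.000389), adipocytes (0.44, adjusted p = 0.0267) and carcinoma epithelium (mean 0.20 ± 0.39 in ovary and -0.19 ± 0.24 in omentum, adjusted p = 0.0267). All 3 had an adjusted p = 0.933 with an estimated correlation.

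B cell genes had lower values in ovary than in omentum CD20 segments (adjusted p = 2.64e-07 with the preset correlation and 0.566 with an estimated correlation), and 0 of 13 members passed when adjusted over the list alone. Ovary segments had more background and less depth. Stronger compression by background was examined with 10000 random lists matched on expression, whose median was -0.09. The list median of -0.53, here not relative to all genes, lay at percentile 0.02 of them. The random lists were drawn gene by gene and lacked the correlation among B cell genes, so the percentile cannot decide. Genes of that expression level were at -0.09 against a median of 0.138 for all genes. Relative to all genes, they were thus lower in ovary too. Shallow segments alone did not give the difference. Without segments under 50000 counts the list mean differed by -0.83 (SE 0.21), against -0.49 (SE 0.24) with all segments. Depth of the remaining segments was not matched between the sites, so other effects of depth stay open. A candidate explanation is a smaller share of B cells against other immune cells in ovary CD20 segments: B cell minus T cell genes were at 0.045 ± 0.21 in ovary and 0.51 ± 0.40 in omentum (SD, n = 6 each; two-sided exact permutation p = 0.028, without a batch term), while T cell genes differed by -0.018 (SE 0.22). It stays a hypothesis, as found and tested on the same specimens, and size of the B cell areas and differences between patients were not tested. The median negative-probe signal was 9.45 in ovary and 7.17 in omentum CD20 segments. The contrast with T cell genes did not remove that background, so it cannot tell a smaller share of B cells from unequal background.

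Fibroblast genes had lower values in ovary than in omentum stroma, with the 4 ovary values below the 6 of omentum (two-sided exact permutation p = 0.0095, without a batch term). The list had an adjusted p = 2.5e-13 with the preset correlation and 0.158 with an estimated correlation. For background, the list median of -2.07, here not relative to all genes, lay at percentile 0 of the random lists, whose median was -0.24. Those lists lacked the correlation among fibroblast genes, so this percentile cannot decide either. A batch difference is argued against by the value within batch 1, -1.514 (SE 0.45), against -1.90 (SE 0.42) over both batches. For replacement of fibroblasts by immune cells, macrophage genes differed by -0.593 (SE 0.27) and T cell genes by -0.070 (SE 0.063). Plasma cell genes differed by 0.12 (SE 0.29). Macrophage and T cell genes thus showed no rise in ovary. The median negative-probe signal was 9.5 in ovary and 8.24 in omentum Stroma segments, so unequal background keeps these values from deciding. With the preset correlation the fibroblast list kept its call without segments under 50000 counts. A difference of the tissues themselves may account for the pattern and remains a hypothesis, as the sites came in part from different donors.

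B cell genes differed little between CD20 and Immune segments, and no explanation could be settled. Without segments under 50000 counts the difference was 0.54 ± 0.59 (SD, 9 specimens) against 0.38 ± 0.48 (SD, 15 specimens), a move smaller than the spread, so an effect of depth cannot be told apart from chance. The batches gave 0.59 ± 0.51, with 7 of 7 specimens higher, and 0.20 ± 0.39, with 6 of 8 higher (two-sided exact permutation p = 0.1139), which leaves a batch difference open. The sites gave 0.68 in omentum, 0.32 in ovary and 0.12 in fallopian tube (permutation p = 0.208), and site and batch are in part confounded, since fallopian tube is in batch 2 only.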

How the results depend on the processing

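The fits without segments of few nuclei or small area and without segments under 50000 counts were chosen after the data had been seen, and the other alternatives before. Over the alternatives other than leaving out specimens, 129 counts of calls stayed within 1.5 times the reported count and 49 did not. Of the values of named genes, 2320 kept their direction and side of the threshold, 99 gained a call, 87 lost it and 26 reversed; of those of lists, 506 kept both, 125 lost the call and 4 reversed. Of the lost list calls, 50 were lost with an estimated correlation, under which 12 of 376 list tests passed instead of 103. Where an alternative changed a result the cause was not tested, except that a stricter filter tests fewer genes and leaving out segments leaves fewer data. Depth limits weak genes most in CD20 segments.

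For Tumor vs Stroma (1026 calls), the count was 350 with the stricter filter, 180 with background subtraction, 3230 with all segments and the specimen as a random block, 2610 in edgeR, 483 without the specimen block, 294 in regions holding both segment types, 1812 without small segments and 1963 without shallow ones. Leaving out 1 specimen gave 567 to 1907. For Immune vs Stroma (416 calls), it was 180 with the stricter filter, 765 with quantile normalisation, 967 with background subtraction, 1442 with the random block, 734 in edgeR and 155 without the specimen block; leaving out 1 specimen gave 252 to 706. For CD20 vs Immune (0 calls), it was 1 with the stricter filter, 1 with background subtraction, 9 with the random block, 90 in edgeR and 24 in batch 1 alone, and 0 to 1 when 1 specimen was left out.

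For Ovary vs Omentum, CD20 (0 calls), the count was 22 with the stricter filter, 587 with the random block, 9 in edgeR and 43 in batch 1 alone, and leaving out 1 specimen gave 0 to 116. For Fallopian Tube vs Omentum, CD20 (0 calls), it was 6 with the random block and 53 in edgeR. For Fallopian Tube vs Ovary, CD20 (0 calls), it was 3 with background subtraction, 35 with the random block, 15 in edgeR and 2 without small segments, and leaving out 1 specimen gave 0 to 460. For Ovary vs Omentum, Immune (0 calls), it was 2 in batch 1 alone and 0 to 1 when 1 specimen was left out. For Fallopian Tube vs Ovary, Immune (0 calls), edgeR gave 1.

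For Ovary vs Omentum, Full ROI (0 calls), the count was 5 with the random block and 1 without small segments, and 0 to 3 when 1 specimen was left out; for Fallopian Tube vs Omentum, Full ROI, it was 0 to 2. For Ovary vs Omentum, Stroma (3 calls), it was 53 with the stricter filter, 145 with background subtraction, 419 with the random block, 45 with quantile normalisation, 5 in batch 1 alone and 5 without shallow segments. It was 0 in edgeR, 0 without small segments, 0 with a pseudocount of 5, 0 without the filter and 0 without the batch term, and 0 to 92 when 1 specimen was left out. For Ovary vs Omentum, Tumor (0 calls), it was 1 with background subtraction, 4 with the random block, 1 with quantile normalisation and 0 to 1 when 1 specimen was left out. For Fallopian Tube vs Omentum, CD20 minus Immune (0 calls), edgeR gave 1. With donor as a random block, the 8 counts of the site comparisons in CD20, Immune and CD20 minus Immune stayed at 0.

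Values that reversed lay near 0 in most cases. For CD20 vs Immune, PTPRC (0.016) was -0.118 with the random block, -0.117 in edgeR, -0.111 in batch 2 alone, -0.273 without small segments and -0.121 without shallow ones, and -0.027 to 0.072 with 1 specimen left out. KRT8 (0.065) was -0.018 with background subtraction, -0.135 with the random block, -0.062 in edgeR, -0.013 without small segments and -0.081 without shallow ones. KRT18 (0.015) was -0.027 with quantile normalisation, -0.163 with background subtraction, -0.08 with the random block, -0.171 in edgeR, -0.063 without small segments and -0.01 without shallow ones, and -0.051 to 0.08 with 1 specimen left out. KRT19 (-0.003) was 0.021 in batch 2 alone and -0.081 to 0.068 with 1 specimen left out. Without small segments RGS13 was -0.047 and IGKC 0.362, and in batch 2 alone the plasma cell list was 0.092. For Immune vs Stroma, MS4A1 was -0.101 with background subtraction and -0.048 without shallow segments; for Tumor vs Stroma it was -0.297 to 0.086 with 1 specimen left out.

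Between sites in CD20 segments, edgeR gave -0.353 for COL1A1 in Fallopian Tube vs Omentum, and -0.358 for COL3A1 and -0.154 for the fibroblast list in Fallopian Tube vs Ovary. In Immune segments, the smooth muscle list of Ovary vs Omentum was -0.009 without small segments, and in Fallopian Tube vs Omentum the macrophage list was -0.03 in edgeR and the complement list -0.015 to 0.613 with 1 specimen left out. For CD20 minus Immune, RPL28 was 0.094 without small segments and MS4A1 0.472 in batch 2 alone in Ovary vs Omentum, and SLC37A2 was -0.209 without small segments in Fallopian Tube vs Omentum.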

Other observations

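The splits of the specimens were planned, and CCL21 was named after its values had been seen. CCL21, a chemokine of lymphoid stroma and lymphatic vessels, was at 5.58 in CD20, 6.38 in Immune and 5.73 in Stroma segments of the lymph node specimen. In the 7 tumour-site specimens of batch 1 it was at most 4.38, 4.51 and 3.78. T cell genes of lymph node Stroma segments were at 4.26 against at most 3.62, and follicular dendritic and reticular cell genes at 4.48 against at most 3.81. The 9 segments named Other came from 1 omentum specimen. They had the 12-chemokine set at 4.77 (4.14 in the CD20 segments of that specimen), T cell genes at 4.24 (3.66) and B cell genes at 4.11 (4.87).

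Further lists were called with the preset correlation only, and those given here are not all of them. Their medians are not relative to that of all genes. In CD20 against Immune segments, genes of type I interferon were lower (median -0.12, adjusted p = 7.34e-05; 0.152 with an estimated correlation), as were TGF-beta and matrix genes (-0.043, adjusted p = 0.0412; 0.165). In Tumor against Stroma segments, genes of T cells (-0.34, adjusted p = 0.00203; 0.238), the 12-chemokine set (-0.50, adjusted p = 0.000991; 0.191) and interferon gamma and antigen presentation (-0.17, adjusted p = 0.00229; 0.21) were lower. In Immune against Stroma segments, TGF-beta and matrix genes (-0.79, adjusted p = 1.19e-05; 0.165) and carcinoma epithelium (-0.22, adjusted p = 0.00732; 0.371) were lower. In ovary against omentum stroma, type I interferon (-0.35; 0.496) and complement genes (-0.47; 0.325) were lower, both with adjusted p = 0.00419. In ovary against omentum CD20 segments, interferon gamma and antigen presentation genes were lower by the test (adjusted p = 0.0488, and 0.664 with an estimated correlation) and by their mean (-0.34). Their median was 0.034, below the 0.138 of all genes. In fallopian tube against omentum CD20 segments, carcinoma epithelium (0.31, adjusted p = 0.00795; 0.362) and regulatory T cell genes (0.28, adjusted p = 0.033; 0.362) were higher.

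Other splits of the same specimens were compared with the real one, by calls past the threshold where there were any and otherwise by genes with an unadjusted p under 0.05. Chance is argued against for Tumor against Stroma, where 1 of 100 drawn splits, the real one, gave 1026 calls and the highest other gave 780. For Immune against Stroma it was 1 of 100 too, but with 416 calls against 411 in the highest other. Not all splits were drawn there and leaving out 1 specimen gave 252 to 706 calls, so chance is not called excluded. Both pairs of segments were chosen by their stains, so some difference between them was built in. For ovary against omentum CD20 segments 2 of 100 splits gave 816 genes or more, the highest other 929, and for stroma 3 of 100 gave 3 calls or more. In stroma the highest other split gave 213 calls, and whether a structure of the specimens gave them was not tested. Chance cannot be excluded for CD20 against Immune segments (455 genes; 28 of 100 splits as many, highest other 1507), fallopian tube against omentum CD20 (399; 59 of 100, 2087) and fallopian tube against ovary CD20 (893; 30 of 100, 3564). Nor can it be in Immune segments for ovary against omentum (277; 70 of 100, 2635), fallopian tube against omentum (207; 100 of 100, 1811) and fallopian tube against ovary (250; 79 of 100, 1189), in Tumor segments by site (226; 30 of 35, 750), or for the difference of CD20 and Immune in ovary (203; 38 of 100, 1601) and fallopian tube (163; 98 of 100, 2418) against omentum. Several of these highest counts were many times the real one. Whether structures of the specimens or correlated genes alone can give such counts was not tested. In Full ROI segments the 8 splits that swap sites within donor numbers are too few for a share under 0.05: the real counts were 586, 324 and 316 and the highest others 1196, 880 and 612, with 5, 5 and 3 splits as large.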
